A study of Danio rerio with 2 samples.

How the data were processed

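The series holds 2 libraries of sorted zebrafish craniofacial cartilage cells, 1 from WT animals and 1 from nkx3.2 mutants. Per the labels, live cells positive for both fli1a:eGFP and sox10:DsRed were captured with the 10x Genomics 3′ Gene Expression kit. The deposited files hold UMI counts per gene and cell barcode, which the authors made with Cell Ranger per the labels; neither its version nor the genome build is given. The matrices held whole numbers only and 35117 genes. Symbols are those of the files, and 4218 entries share a symbol with another; each was kept under its own identifier. The protocol text gives 21 days post fertilization for both libraries, whereas the characteristics give 21 for WT and 22 for the mutant; the characteristics were used.

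The WT library held 2057 barcodes and the mutant library 2005. The filter of at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs removed 0 cells. Scrublet, as run within Scanpy 1.11.5 in each library, called 3 WT and 9 mutant doublets, 0.295% of all barcodes, and these were left out; so low a share leaves doublets of like cells undetected. After the data were examined, 3 WT cells with over 5% globin UMIs were also set apart. The 2051 WT and 1996 mutant cells left were clustered together without integration, from 2000 variable genes, 30 principal components and 20 neighbours, by Leiden at resolution 1 (leidenalg 0.10.2, scikit-learn 1.9.0), giving 15 clusters. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with figures from matplotlib 3.10.9.

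Clusters were named from 13 marker lists chosen before the data were examined. A marker counted as present at 20 CPM or more and at 0.25 or more of its highest cluster level. A cluster took the class with the most markers present, at least 3, unless another class had more markers among its top 10 genes by fold. The numbers in this rule were chosen after the data were examined. Under it clusters 6, 8, 9 and 13 stayed unnamed; clusters 6, 8 and 9 were compared by number, and cluster 13 and the osteoblast-like cells, under 30 cells per library, were not compared.

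For each class and library, UMIs were summed over cells and divided by the class total to give CPM. Sums have exact Poisson intervals, shares exact binomial (Clopper-Pearson) intervals and ratios exact conditional binomial intervals, all at 95% and for counting error only. With 1 library per group no test was run. For log2 ratios a count under 3 was set to 3. Named genes were fixed by a rule before the data were examined: among genes with at least 100 UMIs, without mitochondrial and ribosomal protein genes and without genes under 0.1 of their level in another class of at least 20 cells, the 10 highest and 10 lowest ratios. The rule also took nkx3.2 and up to 4 of the most abundant members of each gene list. The 23 gene lists were fixed at the same time. A list is given by the median log2 ratio of members with at least 20 UMIs and its percentile among 10000 random lists of matched expression, as a description of these libraries. Shares of cells with a UMI were taken after thinning each cell to 3100 UMIs. Genes given per cluster, other than those named by the rule in a class, were chosen after their values were seen.

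The ratio and list methods were tested on simulated data with known folds. In simulated chondrocyte-like counts, a true log2 ratio of 2 was recovered at a median of 2.00 and one of -1 at -0.97, and 96.05% of intervals of unchanged genes held the truth. Of 100 unchanged lists, 6% fell outside the central 95% of random lists. Apart from the set folds, both simulated libraries were Poisson draws from 1 shared profile. The draws held no variation between cells or animals, and the lists were random genes without shared regulation. The simulation therefore checks the computation for counting error and not how intervals or percentiles behave between real libraries.

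Alternatives fixed beforehand were no cell filter, a filter of at least 1000 UMIs and at most 10% mitochondrial UMIs, Scrublet calls kept, Leiden resolutions 0.5 and 2, each library clustered alone, cells called by 2 UMIs over 4 markers, scaling without mitochondrial and ribosomal protein genes, TMM scaling, the mean of per-cell CPM, minimums of 100 UMIs per list member and 300 per named gene, no exclusion of genes far higher in another class, and thinning to 4400 UMIs or not at all. Alternatives added after the data were examined were keeping the globin cells, clustering without 188 variable genes that differ 2-fold between libraries, equal weight per cluster, leaving out cluster 7 and naming cluster 9 chondrocyte-like. For clusters 6, 8 and 9 the alternatives were run on the genes named by ratio, nkx3.2 and 4 lists.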

Results

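Single-cell transcripts were counted in cartilage of juvenile zebrafish, in 1 library from wild-type (WT) animals and 1 library from nkx3.2 mutants. The mutants were homozygous for the el802 allele, and nkx3.2 encodes a homeodomain transcription factor of the developing jaw joint. Live cells carrying both the fli1a:EGFP and the sox10:DsRed reporter had been sorted before capture. Whether all sorted cells derive from the neural crest was not tested. The sample characteristics give 21 days post fertilization for the WT library and 22 for the mutant library, so age differed with genotype by 1 day. The WT library held 2057 cell barcodes and 13927936 unique molecular identifiers (UMIs), with a median of 5781 UMIs per barcode and a range of 1791 to 27090. The mutant library held 2005 barcodes and 16349558 UMIs, with a median of 7005 and a range of 2124 to 38609. Each group was a single library, so no test between genotypes was possible and every interval given is a 95% interval of counting error only. No paired analysis was possible because no 2 libraries shared an animal or a batch that the labels name.

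The targeted gene was measured in both libraries before any other. The nkx3.2 transcript (ENSDARG00000037639) stood at 45.7 CPM (42.2 to 49.4), a UMI count scaled to the total of the cells it came from, in the whole WT library, from 636 UMIs. In the whole mutant library it stood at 41.3 CPM (38.3 to 44.6), from 676 UMIs, a mutant over WT ratio of 0.905 (0.811 to 1.01). In chondrocyte-like cells the level was 37.9 CPM in WT and 40.6 CPM in the mutant, a ratio of 1.07 (0.937 to 1.22). Clusters went both ways: of the 10 clusters with at least 20 UMIs in all, nkx3.2 was higher in the mutant library in 6 and lower in 4, from 9.83 and 41.1 CPM in cluster 1 (23 and 171 UMIs) to the values of cluster 8. Among the classes and numbered groups of at least 30 cells, the highest level was in cluster 8, which expresses genes of hypertrophic cartilage, at 154 CPM in WT and 99.4 CPM in the mutant, a ratio of 0.647 (0.477 to 0.869). The kit reads the 3′ end of transcripts and the position of the lesion is not given in the labels, so a transcript at this level does not check the genotype label in either direction.

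**Figure D1:**
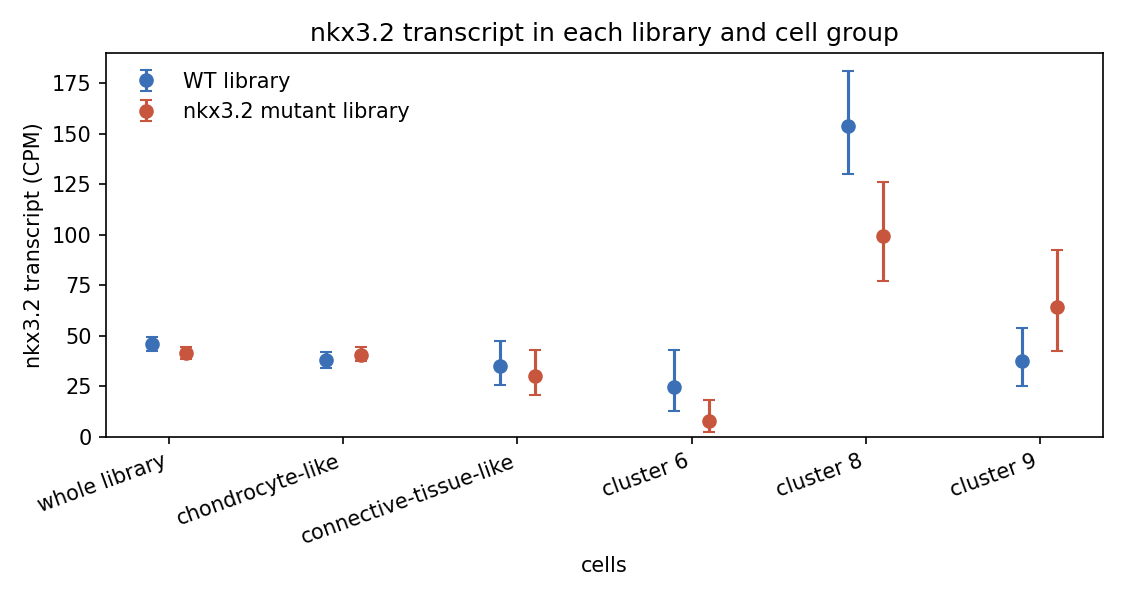
Level of the nkx3.2 transcript in CPM (vertical axis) in each library for the whole library and 5 cell groups; points are summed UMIs over the group's total and bars are exact Poisson 95% intervals. The WT and mutant values were 45.7 and 41.3 CPM in whole libraries and 154 and 99.4 CPM in cluster 8.

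The composition of the sorted cells was compared next. Chondrocyte-like cells, which carry col2a1a, matn1, acana and other cartilage matrix genes, made up 67.1% of WT cells (65.1 to 69.2) and 73.7% of mutant cells (71.7 to 75.6). Connective-tissue-like cells, marked by col5a1, postnb and mfap2, made up 13.4% of WT cells (11.96 to 14.96) and 11.3% of mutant cells (9.92 to 12.7). Osteoblast-like cells, with ifitm5, bglapl and spp1, were 29 WT and 14 mutant cells and were too few to compare. The unnamed cells were 18.0% of WT and 14.3% of mutant cells. Among them, cluster 8 (mmp13b, spp1, col10a1a, ihha) held 5.66% of WT cells (4.70 to 6.74) and 3.76% of mutant cells (2.97 to 4.69). Cluster 9 (six2a, mdka, cxcl18b) held 5.46% and 3.26%, cluster 6 (ccl25b, cxcl12a, rgs5a) held 5.51% and 6.61%, and cluster 13 (krt4, cfd, icn) held 1.41% and 0.701%. The naming rule bears on these shares: unnamed clusters 8 and 9 had 10 and 11 chondrocyte markers present, whereas cluster 5, counted as chondrocyte-like, had 3. With cluster 9 named chondrocyte-like, the chondrocyte-like shares were 72.6% in WT and 76.95% in the mutant. The order of the chondrocyte-like shares depended on the clustering: at Leiden resolution 2.0 they were 63.9% in WT and 58.9% in the mutant, and with cells called by 4 cartilage markers they were 90.5% and 90.6%. A stricter filter, which only 1 WT and 0 mutant cells fail, gave 71.1% and 76.4%, both outside the counting intervals above. Those intervals therefore leave out the uncertainty of clustering and naming. The sort gate and the dissociation also set these shares.

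In chondrocyte-like cells (1377 WT, 1471 mutant), genes for folding and modifying secreted proteins in the endoplasmic reticulum and genes for cartilage matrix were lower in the mutant library. The disulfide isomerase gene pdia6 had a mutant over WT ratio of 0.227 (0.190 to 0.268), the chaperone gene hyou1 0.179 (0.102 to 0.297) and manf, which encodes a secreted factor induced by unfolded proteins, 0.238 (0.191 to 0.295). The collagen gene col2a1a, which encodes the main fibrillar collagen of cartilage, had a ratio of 0.571 (0.567 to 0.575), and the matrilin gene matn1 0.594 (0.589 to 0.599). Both genes also served to name the class. Both were lower in 11 of the 12 clusters of at least 30 cells per library. Their log2 ratios were -0.49 and -0.44 in cluster 0 and -0.60 and -0.30 in cluster 1. Clusters 0, 1 and 7 were unevenly spread between the libraries, so cluster mix may carry a part of the class ratios. In the other direction, sesn1, which encodes a sestrin that restrains mTORC1 signalling, was 4.75-fold higher in the mutant library (4.28 to 5.28), and ulk2, which encodes a kinase that starts autophagy, was 4.90-fold higher (3.62 to 6.76). The log2 ratio of sesn1 was 2.25, and 1.65 with equal weight per cluster; sesn1 also leads cluster 7, which is mutant cells almost throughout. Within the 12 clusters of at least 30 cells per library its log2 ratio ran from 0.19 to 2.70, and the lowest was in cluster 0, with 74 WT and 38 mutant UMIs at 23.8 and 27.1 CPM.

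The endoplasmic reticulum folding list had a median log2 ratio of -0.98, and 24 of its 25 measured members were lower in the mutant library. Its median lay at percentile 0 of 10000 random lists matched on expression, as did those of the cartilage matrix, fibrous matrix, immediate early and mitochondrial genome lists, and 11 of the 23 lists lay below percentile 2.5. Ribosomal protein genes took a median of 47.3% of UMIs per cell in WT and 52.4% in the mutant. The collagen chaperone gene serpinh1b had a ratio of 0.358 (0.344 to 0.372), the prolyl hydroxylase subunit gene p4hb 0.597 (0.576 to 0.619), and the stress transcription factor gene xbp1 0.650 (0.630 to 0.670). Within the 12 clusters that had at least 30 cells in each library, the list median was below 0 in 12, from -1.29 to -0.37.

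The cartilage matrix list had a median log2 ratio of -0.67, with 20 of 21 measured members lower and a percentile of 0. The collagen gene col9a3 had a ratio of 0.629 (0.622 to 0.636) and lect1, the gene for chondromodulin, 0.670 (0.663 to 0.677). The same list was below 0 in 11 of the 12 clusters, and stood at 0.14 in cluster 6, where its leading genes were low enough to be free RNA. The perichondrium and fibrous matrix list stood at -0.75 with 18 of 19 members lower, including fn1b at a ratio of 0.591 (0.567 to 0.616). Among cartilage transcription factors, with a list median of -0.42, sox6 had a ratio of 0.671 (0.632 to 0.712) and sox5 0.749 (0.673 to 0.833).

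In chondrocyte-like cells, which leave out the unnamed cluster 8, 6 of the 8 measured genes of cartilage hypertrophy were lower in the mutant library. The collagen gene col10a1a, a marker of hypertrophic chondrocytes, had a ratio of 0.220 (0.204 to 0.237), and the collagenase gene mmp13b 0.358 (0.294 to 0.433), with log2 ratios of -1.48 and, for cells called by 4 cartilage markers, -2.58. The parathyroid hormone receptor gene pth1ra had 0.630 (0.562 to 0.705), while the matricellular gene ctgfa was 1.64-fold higher in the mutant library (1.58 to 1.71). The list's median was -0.52, at percentile 1.98. The log2 ratio of col10a1a was -2.19 over all cells of the class and -1.55 with equal weight per cluster. After thinning every cell to 3100 UMIs, col10a1a was seen in 10.7% of WT chondrocyte-like cells (9.08 to 12.6) and 4.76% of mutant ones (3.70 to 6.02). Without thinning the shares were 17.6% and 8.09%. The thinned shares in connective-tissue-like cells, which should lack the gene, were 5.97% and 4.05%. Most col10a1a UMIs of the class came from cluster 5, with 2770 of 3030 in WT and 784 of 874 in the mutant, at 3220.1 and 1114.6 CPM. Over both libraries mmp13b, ihha and spp1 had 3, 0 and 33 UMIs in cluster 5, against 4930, 131 and 4408 in cluster 8. In cluster 8, which col10a1a and mmp13b help to define, the hypertrophic list had a median of -0.37 at percentile 12.9, with 6 of 9 members lower. Median depths were 6422 (WT) and 8173 (mutant) UMIs in chondrocyte-like and 4086 and 4114 UMIs in connective-tissue-like cells, and thinning left out 130 WT and 85 mutant chondrocyte-like cells. Thinned shares of mmp13b, at 4.81% and 1.88%, were below those in connective-tissue-like cells, at 7.96% and 6.36%. Over both libraries the highest mmp13b level in a chondrocyte-like cluster was 78.8 CPM, in cluster 0, against 3049.8 CPM in cluster 8. For spp1 these levels were 41.0 CPM, in cluster 4, and 2726.9 CPM. UMIs of mmp13b and spp1 in the class may be free RNA from other cells, which was not tested. Their ratios therefore need not reflect expression by chondrocyte-like cells. Whether cells called by 4 markers include cluster 8 cells was not tested either.

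Joint genes gave few UMIs. The joint and articular surface list had a median log2 ratio of -0.45, with 9 of 13 measured members lower, at percentile 3.26. Its most abundant member fibinb was 1.30-fold higher in the mutant library (1.19 to 1.43), and barx1, a homeobox gene that represses joint formation, had a ratio of 1.03 (0.759 to 1.40). The lubricin gene prg4b was seen in 0.481% of thinned WT cells (0.177 to 1.04) and 1.30% of thinned mutant cells (0.771 to 2.04). Its UMIs in the class were 19 in WT and 49 in the mutant, and cluster 4 (159 WT, 184 mutant cells) held 62 of them. Without thinning these shares were 0.654% and 2.31%, and the shares in connective-tissue-like cells were 0 of 201 in WT and 0 of 173 in the mutant after thinning. The joint factor gene gdf5 was seen in 0.481% and 0.289% of thinned cells and in 1.02% and 1.09% of cells without thinning, and the difference was not detectable at this depth; 2 of 201 and 0 of 173 thinned connective-tissue-like cells had it.

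Most genes of the circadian clock and 2 homeobox genes of the arches were higher in the mutant library. The clock list had a median log2 ratio of 0.48, at percentile 99.92, with 14 of 21 members higher. Within the 12 clusters the clock median was above 0 in 9 and below 0 in 3, from -0.91 to 0.50. Its members tefa and cry1aa were 1.53-fold (1.36 to 1.73) and 1.40-fold (1.15 to 1.70) higher, while bhlhe40 had a ratio of 0.820 (0.729 to 0.923). The paired-type homeobox genes prrx1a and prrx1b were 2.19-fold (1.96 to 2.46) and 2.37-fold (2.01 to 2.81) higher; the log2 ratio of prrx1b was 1.25, and 0.62 with equal weight per cluster. The jaw and arch patterning list as a whole had a median of 0.04. Immediate early genes had a list median of -0.67, with 19 of 24 members lower, and fosab had a ratio of 0.541 (0.517 to 0.567). Within the 12 clusters the immediate early median was below 0 in 12, from -0.67 to -0.02. With equal weight per cluster the median in the class was -0.51. Mitochondrial genome transcripts had a median of -0.72, and ribosomal protein genes a median of 0.18.

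The largest single-gene ratios included genes with no list. The glutathione peroxidase gene gpx4a was 9.87-fold higher in the mutant library (7.31 to 13.6), and si:dkey-104n9.1 had 0 UMIs in WT and 125 in the mutant, 31.7-fold higher with the WT count set to the floor of 3 UMIs. The cholesterol exporter gene abca1a was 4.35-fold higher (2.96 to 6.60), with a log2 ratio of 2.12, and of 1.21 for cells called by 4 cartilage markers. The lowest ratio was that of tcap, which encodes a sarcomere protein, at 0.0588 (0.0348 to 0.0939) from 246 and 19 UMIs; 1 WT cell held 37.4% of its WT UMIs, and its log2 ratio of -4.09 was -3.05 with equal weight per cluster. The lymphotoxin-family gene tnfb had a ratio of 0.161 (0.111 to 0.228; 1 WT cell held 11.4% of its WT UMIs), the phosphatase gene dusp2 0.183 (0.139 to 0.239) and the mitochondrial folate enzyme gene mthfd2 0.211 (0.140 to 0.310). The log2 ratio of dusp2 was -2.45, and -0.75 with equal weight per cluster. The cell groups were not evenly spread: cluster 0 held 422 WT and 209 mutant cells, cluster 1 held 201 and 374, and cluster 7 held 2 and 208. Values within the class therefore weight these clusters differently in the libraries.

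**Figure D2:**
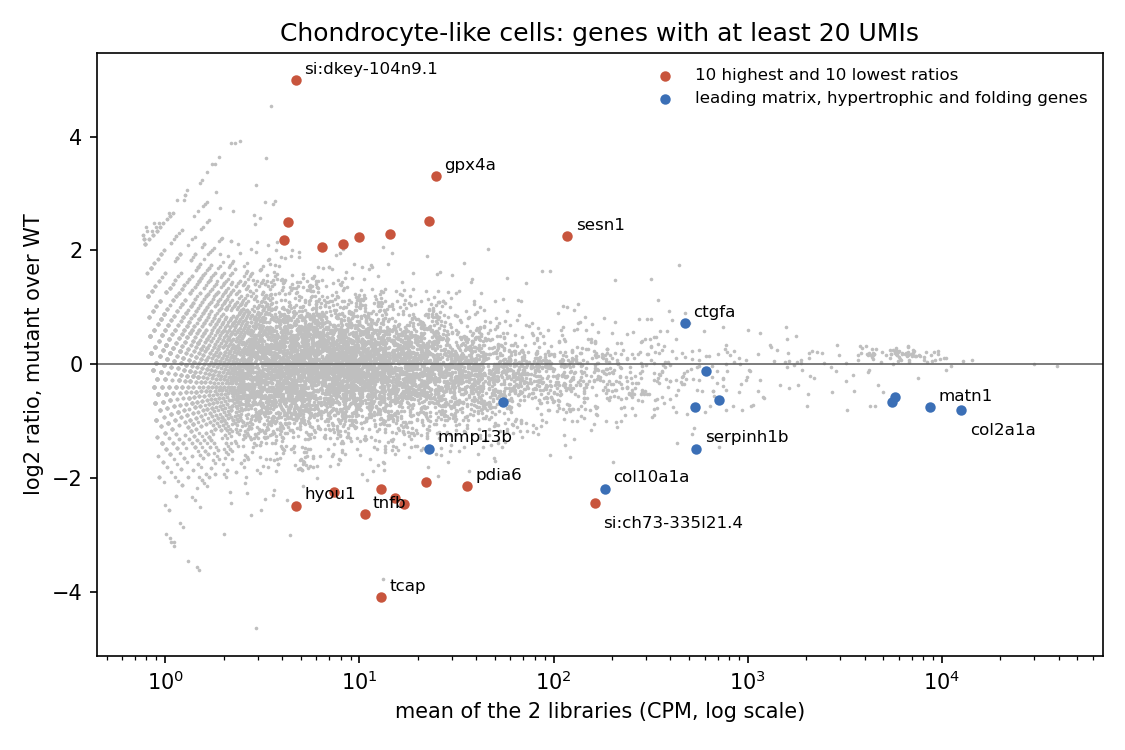
Log2 ratio of mutant over WT (vertical axis) against the mean of the 2 libraries in CPM (horizontal axis, log scale) for genes with at least 20 UMIs in chondrocyte-like cells, with counts under 3 set to 3. Red points are the 10 highest and 10 lowest ratios among genes open to naming, among them sesn1 at 4.75-fold and tcap at 0.0588; blue points are leading members of 3 lists, among them col2a1a at 0.571.

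In connective-tissue-like cells (275 WT, 225 mutant), folding genes and fibrous matrix genes were again lower in the mutant library, and sesn1 was again higher. The gene sesn1 was 4.65-fold higher (3.17 to 6.99), and akt1s1, which encodes an inhibitory subunit of mTORC1, was 3.59-fold higher (2.56 to 5.13). The interferon-induced membrane gene ifitm1 was 3.30-fold higher (2.99 to 3.63), and the lipoprotein lipase gene lpl 2.99-fold (2.02 to 4.50). The LIM domain gene crip1 had the lowest ratio, 0.206 (0.157 to 0.266), followed by angptl7 at 0.304 (0.237 to 0.387) and pdia6 at 0.318 (0.191 to 0.508). The genes ifitm1, crip1 and angptl7 were also among the top 10 genes of unnamed cluster 6, which had 10 connective tissue markers present. Whether the boundary with that cluster bears on the ratios of ifitm1, crip1 and angptl7 was not tested. The chaperone gene hsp90b1 had a ratio of 0.355 (0.263 to 0.475).

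The endoplasmic reticulum folding list had a median log2 ratio of -0.95 in these cells, with 22 of 24 members lower. The fibrous matrix list had -0.57 with 17 of 17 members lower, at percentile 0.47. The collagen gene col1a2 had a ratio of 0.571 and col1a1a, which encodes its partner chain, 0.579. The osteoblast and bone matrix list, led by sparc and type I collagen genes, had -1.11 with 7 of 7 lower, and the cell cycle list -0.81 with 12 of 13 lower. The jaw and arch patterning list had a median of 0.39, at percentile 99.96, with msx1b and pou3f3a 1.87-fold and 1.74-fold higher, and the clock list had 0.37, at percentile 99.93. The median over all genes was -0.26 in this class, and TMM scaling moved every log2 ratio by 0.24 upward relative to CPM. Relative to that scaling the folding list stood at -0.72 and the fibrous matrix list at -0.33, while the medians of the TGF-beta, matrix remodelling, inflammation and immediate early lists turned from below to above 0. The gene s100a11 had 2 UMIs in WT and 178 in the mutant, a ratio of 106 (28.9 to 880), but its log2 ratio, 6.14 with the floor of 3, was 4.55 with every cell at equal weight and 0.28 when clusters were built without genes that differ 2-fold between libraries.

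**Figure D3:**
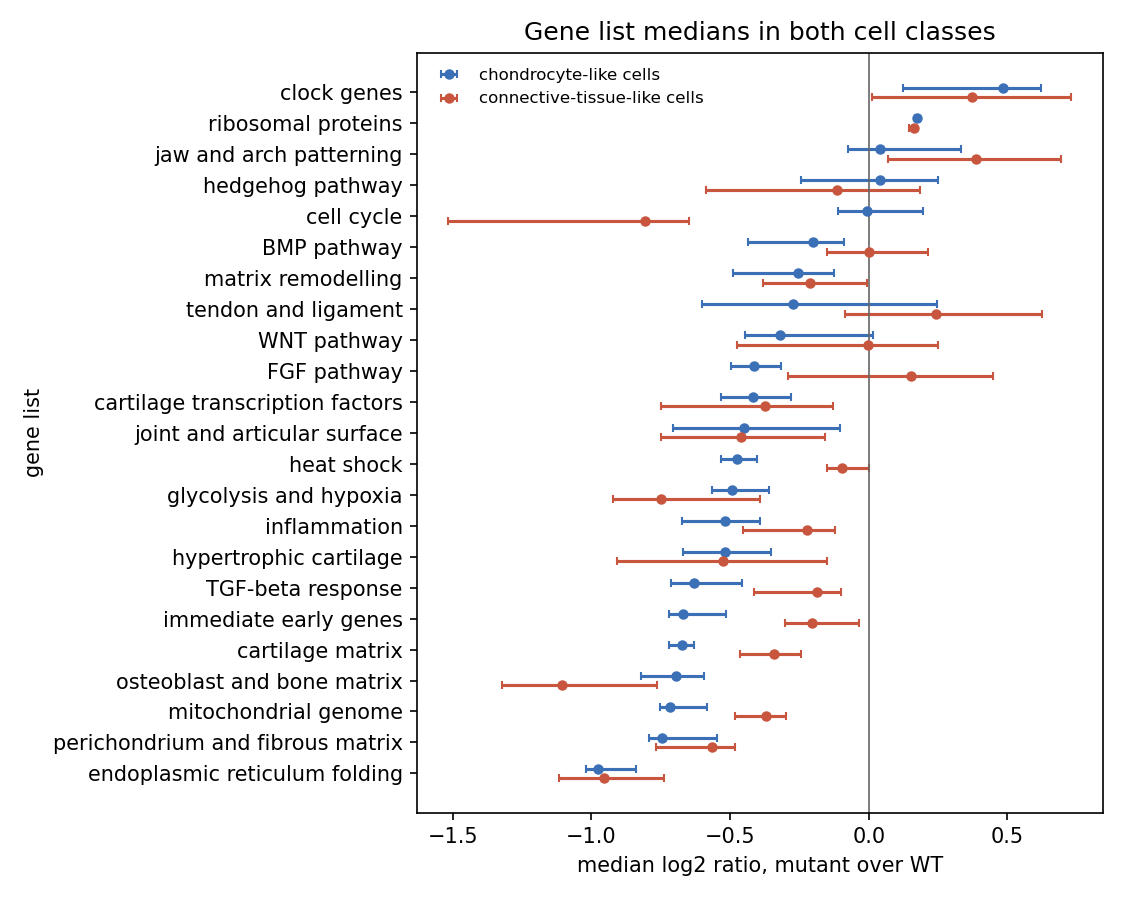
Median log2 ratio of mutant over WT (horizontal axis) for 23 gene lists in chondrocyte-like and connective-tissue-like cells; bars are 95% ranges of the median over 1000 Poisson draws of the counts. The endoplasmic reticulum folding list had the lowest median in chondrocyte-like cells, -0.98, and stood at -0.95 in connective-tissue-like cells.

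The unnamed clusters with enough cells were compared by number. In cluster 8 (116 WT, 75 mutant), the prostaglandin synthase gene ptgdsb.1 was 9.18-fold higher in the mutant library (7.96 to 10.6) and sesn1 6.51-fold (4.87 to 8.82), whereas acta2, the smooth muscle actin gene, had a ratio of 0.0861 (0.0364 to 0.175). The gene ptgdsb.1 was also among the top 10 genes of cluster 5. With every cell at equal weight the log2 ratio of acta2 was -2.71 instead of -3.54. The differentiation inhibitor gene id2b had a ratio of 0.265 (0.160 to 0.421) and the growth factor gene mdka 0.2995 (0.228 to 0.389). The log2 ratio of sesn1, 2.70 here, was 3.38 at resolution 2.0 and 3.43 with clusters built without genes that differ 2-fold between libraries. The cartilage matrix list had a median of -0.55 and the folding list -0.62. In cluster 6 (113 WT, 132 mutant), sesn1 was 2.92-fold higher (1.81 to 4.90) and akt1s1 2.30-fold (1.47 to 3.69). There, the prostaglandin synthase gene ptgs2a had a ratio of 0.311 (0.220 to 0.434) and the fibrous matrix list a median of -0.70. The cartilage matrix list went the other way in cluster 6, with a median of 0.14, 13 of 17 members higher and percentile 99.57. With Scrublet calls kept that median was 1.01. Matrix genes were scarce there: col2a1a and matn1 each stood at 261.9 CPM over both libraries, against 21458 and 17305.2 CPM in cluster 0. Such levels are under the 0.1 limit of the naming rule. They may be free RNA from other cells, which was not tested for this list. In cluster 9 (112 WT, 65 mutant), eif4ebp3, which encodes a repressor of cap-dependent translation, was 2.24-fold higher (1.87 to 2.70). The zinc finger gene klf6a had a ratio of 0.379 (0.218 to 0.627; log2 ratio -1.40, and -0.50 at resolution 0.5) and the cartilage matrix list a median of -0.82.

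**Figure D4:**
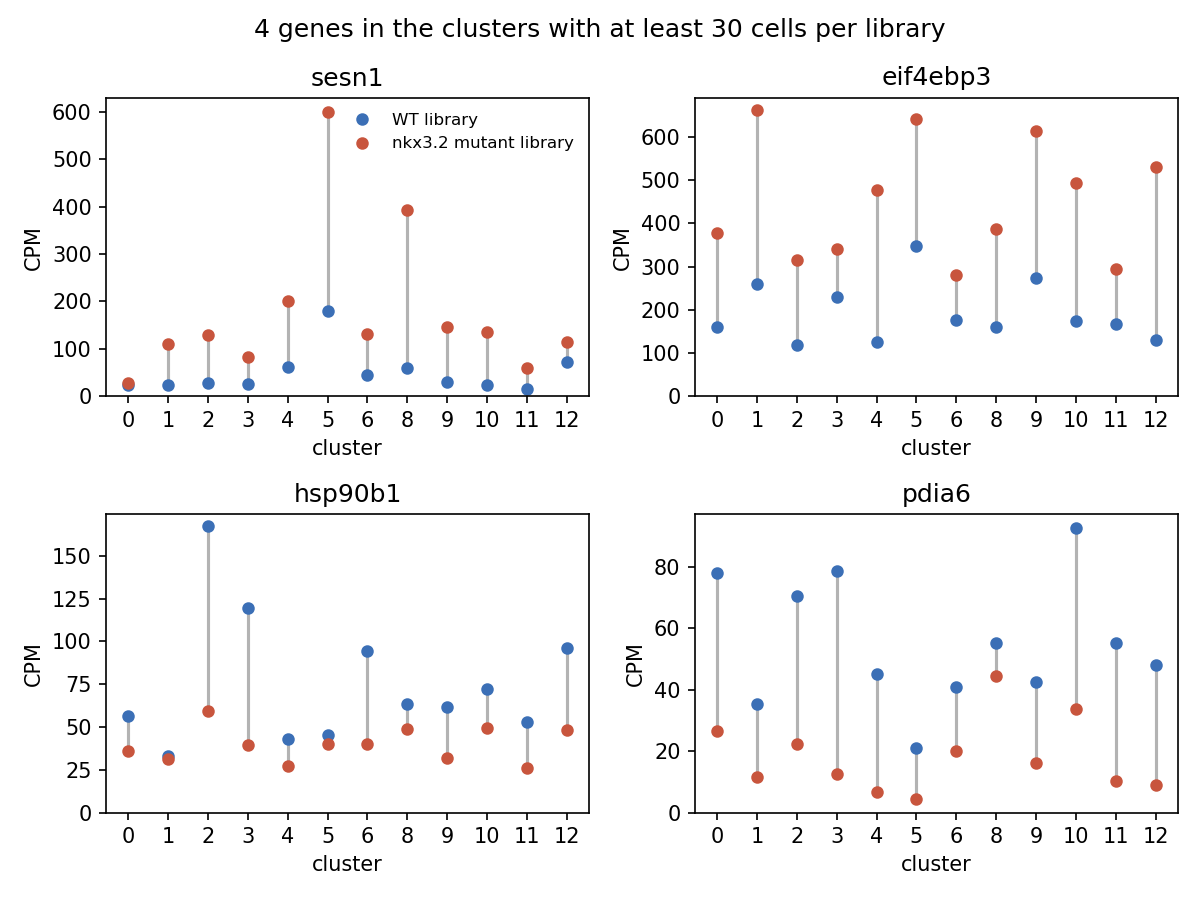
Level of 4 genes in CPM (vertical axes) in the WT and mutant libraries for the 12 clusters with at least 30 cells in each library (horizontal axes); each line joins the 2 values of a cluster. For sesn1 and eif4ebp3 the mutant value was higher in 12 of 12 clusters, though by a log2 ratio of only 0.19 for sesn1 in cluster 0. For hsp90b1 the mutant value was lower in 12 of 12, though by a log2 ratio of only -0.065 in cluster 1. For pdia6 it was lower in 11 of the 11 clusters with at least 20 UMIs.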

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

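Of the tests below, those on cluster mix, handling stress, free RNA, scaling and the nkx3.2 locus, and the run without cluster 7, were chosen only after the result was seen; those on depth, on the fasting list and on single cells were set before their values were computed.

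In 6 named genes the ratio lay above 1 in one class and below 1 in the other, beyond counting error; these differences between classes were not tested. The log2 ratios in chondrocyte-like and then connective-tissue-like cells were 0.38 and -0.51 for fibinb and -0.89 and 0.19 for fosab. They were -0.34 and 2.25 for tmsb1, the latter 1.23 with clusters built without genes that differ 2-fold, and -0.29 and 0.88 for bhlhe40. The gene tmsb1 had 25 and 100 UMIs in connective-tissue-like cells and was also among the top 10 genes of cluster 5. Whether cells or RNA of cluster 5 bear on its ratio there was not tested. The log2 ratios were -0.11 and 0.22 for mmp2 and -0.11 and 0.24 for id2a. The chondrocyte-like value of both mmp2 and id2a turned above 0 with scaling that leaves out mitochondrial and ribosomal protein genes. Outside the compared cells, 3 WT cells carried 78.9% of their UMIs on globin genes, against at most 0.0570% in any other cell.

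The genes sesn1, eif4ebp3, akt1s1, pik3ip1, ulk2 and lpin1, most of which encode restraints on growth signalling or starters of autophagy, had a median log2 ratio of 1.84 in chondrocyte-like cells; this set was picked because of its values. Deeper cells differed from shallower cells of the same library by -0.78 in WT and 0.19 in the mutant, which met the limit set before. That split also sorts cell types, so alone it does not decide on depth. In clusters 0, 1, 5 and 9 mutant cells were not deeper than WT cells by median UMIs. There the measured genes still had medians of 0.94, 1.79, 1.26 and 1.13, a comparison added afterwards. These values argue against depth per cell in those clusters. The tables argue against cluster mix as the whole cause, since the lowest of 12 cluster medians was 0.94. The median over these clusters was 1.23, so mix may carry a part of the 1.84. Cluster 7 (2 WT, 208 mutant cells), with sesn1, eif4ebp3, akt1s1, pik3ip1 and lpin1 among its top 10 genes, is not among the 12. Free RNA is argued against too: the genes' lowest cluster level was 0.420 of the pooled level, while the abundant gene otos allows 0.0197. Lower nutrient supply stays a candidate explanation that the test left undecided: 34 other fasting and FOXO targets, some with values already seen, had a median of 0.18 at percentile 99.42, which meets the limit set before, but 0.04 at percentile 87.53 without cluster 7, a condition added afterwards, and 13 of the 23 fixed lists also lay outside the central 95%. Handling stress stays open too: the immediate early median was below 0 in 12 of 12 clusters and the pooled heat shock median was -0.47, but the heat shock median reached 0.47 in cluster 0, and genotype, the age gap of 1 day, feeding and library preparation cannot be separated with 1 library per group.

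The endoplasmic reticulum folding genes were lower in both classes, with a median log2 ratio of -0.98 in chondrocyte-like cells. In neither library were deeper cells below shallower ones, the lower value being 0.014, but that split also sorts cell types. In clusters 0, 1, 5 and 9, whose mutant cells were not deeper, the list medians were -0.62, -0.67, -0.56 and -0.49. These values, compared afterwards, argue against depth per cell in those clusters. Cluster mix as the whole cause is argued against by the highest of 12 cluster medians, -0.37. Mix may still carry a part, since the median was -0.76 without cluster 7 and -0.80 with equal weight per cluster. Scaling is argued against by the higher median under the other scalings, -0.83. Genotype, age and handling stay open and untested.

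In chondrocyte-like cells 26 genes eligible for naming were at least 4-fold apart, 14 higher and 12 lower in the mutant library. Of the 24 that could be placed in the reference, 0 lay among the 100 genes on either side of nkx3.2 and 0 on its chromosome, which argues against variants linked to that locus as the source of most. A few cells with many UMIs are argued against for the set by a median largest-cell share of 2.80%, though single cells held 37.4% for tcap, 28.4% for wu:fj16a03, 23.4% for si:ch211-69g19.2, 11.4% for tnfb and 10.3% for si:dkey-225n22.4. Unlinked variants between the fish of the libraries, which can alter how reads are assigned, were not tested, since the counts hold no sequence.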

How the results depend on the processing

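Each alternative was set against the values of the report. The values below are all that turned direction, counted where the interval of the main value lies on 1 side of 0. Also given are those of the leading results that moved, which means left that interval. Unless stated, the cause was not tested. Of 3260 gene ratios under the alternatives, 2782 stayed, 458 moved and 20 turned direction. Of 725 list medians, 623 stayed, 98 moved and 4 turned direction. Where the interval holds 0, 95 gene ratios and 26 list medians took the other sign, among them nkx3.2 in connective-tissue-like cells, from -0.22 to 0.39 with clusters built without genes that differ 2-fold, and the tendon and ligament list in chondrocyte-like cells, from -0.27 to 0.41 with at least 100 UMIs per member. For clusters 6, 8 and 9 only the genes named by ratio, nkx3.2 and 4 lists were recomputed. Of the 20 genes named in chondrocyte-like cells, a minimum of 300 UMIs keeps 9.

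With at least 1000 UMIs and at most 10% mitochondrial UMIs per cell the chondrocyte-like share was 71.1% in WT and 76.4% in the mutant. There, the connective-tissue-like share was 15.3% in WT and the unnamed share was 12.2% in WT and 10.9% in the mutant. Only 1 WT and 0 mutant cells fail this filter. These moves therefore come from how the cells were clustered and named anew, not from the cell lost. With Scrublet calls kept, which adds 3 WT and 9 mutant cells, the chondrocyte-like share was 72.5% in WT and 76.96% in the mutant. The unnamed share was then 12.2% in WT and 10.9% in the mutant. At Leiden resolution 2.0 the chondrocyte-like share was 63.9% in WT and 58.9% in the mutant and the unnamed share was 20.9% in WT and 29.01% in the mutant. There, the list median in chondrocyte-like cells of cell cycle was 0.23. There, the log2 ratio in cluster 6 of f13a1b was -0.0292. At Leiden resolution 0.5 the connective-tissue-like share was 18.6% in WT and 14.5% in the mutant and the unnamed share was 11.9% in WT and 10.5% in the mutant. There, the list median in connective-tissue-like cells of perichondrium and fibrous matrix was -0.47. There, the log2 ratio in cluster 6 of f13a1b was -0.0292. With cluster 9 named chondrocyte-like the chondrocyte-like share was 72.6% in WT and 76.95% in the mutant and the unnamed share was 12.6% in WT and 11.1% in the mutant. With cells called by 4 markers the chondrocyte-like share was 90.5% in WT and 90.6% in the mutant. There, the list median in chondrocyte-like cells of hypertrophic cartilage was -0.91. With clusters built without genes that differ 2-fold the osteoblast-like share was 4.58% in WT and 3.06% in the mutant and the unnamed share was 12.3% in the mutant. There, the log2 ratio in connective-tissue-like cells of mmp13b was 0.47. There, the log2 ratio in cluster 6 of f13a1b was -0.87. With each library clustered alone the chondrocyte-like share was 76.1% in the mutant.

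Scaled without mitochondrial and ribosomal protein genes nkx3.2 stood at 89.2 CPM in WT and 89.9 CPM in the mutant. There, list medians in chondrocyte-like cells were cartilage matrix -0.52, endoplasmic reticulum folding -0.83 and clock genes 0.63. There, the list median in connective-tissue-like cells of perichondrium and fibrous matrix was -0.43. There, log2 ratios in chondrocyte-like cells were id2a 0.0349, mmp2 0.038, timp2a 0.00805, hsp90ab1 0.0334 and sec61b 0.0299. Under TMM scaling, the list median in chondrocyte-like cells of cartilage matrix was -0.62. There, list medians in connective-tissue-like cells were perichondrium and fibrous matrix -0.33, TGF-beta response 0.0504, matrix remodelling 0.0271, inflammation 0.014, immediate early genes 0.0314 and endoplasmic reticulum folding -0.72. There, log2 ratios in connective-tissue-like cells were col9a3 0.0517, cxcl18b 0.00442, hsp90ab1 0.0872, hspa8 0.0554 and mt-co2 0.016. With every cell at equal weight nkx3.2 stood at 49.7 CPM in WT and 45.1 CPM in the mutant. There, the list median in chondrocyte-like cells of cartilage matrix was -0.59. With equal weight per cluster, list medians in chondrocyte-like cells were cartilage matrix -0.53, hypertrophic cartilage -0.25, immediate early genes -0.51, endoplasmic reticulum folding -0.80 and cell cycle 0.29. There, log2 ratios in chondrocyte-like cells were dlx5a 0.0153, sufu -0.15, wif1 0.12, mmp2 0.0722 and pcna 0.0502. Without cluster 7, list medians in chondrocyte-like cells were cartilage matrix -0.58, endoplasmic reticulum folding -0.76 and cell cycle 0.29. There, the log2 ratio in chondrocyte-like cells of mmp2 was 0.0329. With at least 100 UMIs per list member, list medians in chondrocyte-like cells were immediate early genes -0.50 and cell cycle -0.28. There, the list median in connective-tissue-like cells of endoplasmic reticulum folding was -0.68.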

Other observations

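Several further genes were compared within the clusters; they were chosen after their values were seen. The translation repressor gene eif4ebp3 and the mTORC1 inhibitor gene akt1s1 were higher in the mutant library in 12 of 12 clusters, pik3ip1 in 8 of the 8 clusters with at least 20 UMIs, and the phosphatidate phosphatase gene lpin1 in 11 of 12, with a log2 ratio of -0.997 in cluster 12. Over all chondrocyte-like cells eif4ebp3 was 3.33-fold higher (3.18 to 3.50) and pik3ip1 3.75-fold (3.005 to 4.73). The peroxidase gene gpx4a was higher in 11 of the 11 clusters with at least 20 UMIs. The gene si:ch73-335l21.4 was lower in 12 of 12, from -4.10 to -0.20 on the log2 scale.

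Other fixed lists in chondrocyte-like cells had medians of -0.63 for TGF-beta response, -0.52 for inflammation, -0.49 for glycolysis and hypoxia and -0.69 for osteoblast and bone matrix. The heat shock list had -0.47, but within clusters its median was above 0 in 3 and below 0 in 9 of 12, from -1.36 in the stress cluster 12 to 0.47 in cluster 0. Medians were -0.41 for the FGF, -0.32 for the WNT, -0.20 for the BMP and 0.04 for the hedgehog pathway, -0.25 for matrix remodelling, -0.27 for tendon and ligament (0.41 with at least 100 UMIs per member) and -0.00464 for cell cycle. The cell cycle members went both ways, 11 higher and 13 lower; among genes chosen after their values were seen, the mitotic genes plk1 (5 and 81 UMIs) and cdk1 (8 and 76 UMIs) had log2 ratios of 3.63 and 2.86, and the replication genes mcm6 and rrm1 -0.85 and -0.87. Of the plk1 UMIs, 76 lay in the dividing cluster 10 (58 WT, 113 mutant cells), so its ratio over the class also carries the unequal size of that cluster. Within the immune signalling genes, cxcl18b had a ratio of 0.525 (0.501 to 0.551), while the cytokine signalling inhibitor socs3b was 1.44-fold higher (1.36 to 1.52). The target id1 of BMP signalling had a ratio of 0.590 (0.564 to 0.617).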
